A study of Mus musculus with 103 samples.

How the data were processed

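Mouse embryonic fibroblasts (MEFs) of the C57BL/6 strain, taken at embryonic day 13.5 and held in quiescence, were profiled by RNA-seq, by global run-on sequencing (GRO-seq) and by ChIP-seq. RNA-seq measured polyadenylated RNA. GRO-seq measured RNA that engaged polymerases extended in isolated nuclei with a bromouridine analog, which was then enriched with an antibody. The sample list held 103 samples, of which 29 were RNA-seq and 10 were GRO-seq. The ChIP-seq samples were not analysed here. The cells carried conditional (floxed) alleles of Ctcf, Smc3, Wapl or both Ctcf and Wapl. Per the labels, Smc3 and Wapl were deleted by 2 to 3 d of hydroxytamoxifen, which activates a Cre-ER recombinase expressed from Rosa26. Ctcf, alone or with Wapl, was deleted by a 4 h exposure to an adenovirus that expresses Cre (Adeno-Cre). The cells of the RNA-seq and GRO-seq samples were then rested for 10 d. Wild-type cells with Adeno-Cre and Cre-ER cells without a floxed gene served as controls for the ways of inducing Cre.

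The authors deposited RNA-seq values as RPKM, read counts scaled to gene length and library size, for 23339 RefSeq genes in 27 libraries of 12 groups. Each library was scaled on its own, per the file headers and values. RPKM values of 2 further libraries of Ctcf and Wapl floxed cells were deposited in a separate table, which had been normalized apart from the larger one and held 529 repeated entries. GRO-seq values were deposited as TPM, per the file headers, with 2 libraries pooled in each column for the untreated and the Adeno-Cre condition of the Ctcf and Wapl floxed cells. The DRB and DRB washout columns held 1 library each and summed to 100000, against 200000 for the pooled columns. They were therefore multiplied by 2.0 before any comparison. Such values are shares of a fixed total, so a general loss of transcription cannot appear in them. Wild-type GRO-seq was deposited as 1 pooled TPM column, whose source libraries were not given in the sources used here, so no wild-type GRO-seq comparison was made. Per the submitters' processing notes, the genome build was mm9 and the tools were TopHat 1.3.1 and 1.4.1, Bowtie 0.12.5, MACS 1.4.2, HTSeq and bedtools, with no role or order stated. Whether counting used strand was not given in the sources used here, so overlapping antisense genes cannot be told apart. The number of columns of per-sample values left unused was 0.

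Depth was recovered from the RPKM values. For 18146 of 18155 genes with a value above 0 in at least 3 libraries (99.95%), the values were whole multiples of a step within a tolerance of 0.02 reads. The libraries held 7.5 M to 37.8 M reads in genes. An RPKM of 1 for a gene of median length corresponded to 22.5 to 109.0 reads, depending on the library. The depth of the GRO-seq columns is unknown.

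Differences were tested with limma 3.58.1 in R 4.3.3 (linear model, contrasts, empirical Bayes with trend and robust options) on log2(RPKM + 1). Fold changes are on that scale, which understates the change of genes with low values. Genes with RPKM of at least 1 in at least 2 libraries were tested, which left 12604. A single model over the 27 libraries, with 1 mean per group and 15 residual degrees of freedom, gave every comparison a shared estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Differences between 2 comparisons were tested as contrasts of contrasts in the same model. The replicates are clones of embryonic fibroblasts, and treated and untreated libraries of the same number come from the same clone per the labels. Wild-type and Ctcf floxed libraries held both Xist (0.429 to 1.82 RPKM) and the Y-linked Ddx3y (2.21 to 4.07 RPKM). What the labels call a clone therefore need not be cells of 1 sex. In the 4 Smc3 pairs of a clone, the deviations of the treated and untreated library from their group means correlated at 0.49 to 0.70. With 2 libraries per group both pairs give the same value by construction. It was 0.68 for Ctcf, 0.47 for Wapl and 0.76 for wild-type cells. In the 2 Cre-ER pairs the correlation was -0.20, so those labels' clone numbers were also tried crossed. A model with the clone as a block (7 residual degrees of freedom) was an alternative. Replicate libraries of a group correlated at 0.948 to 0.991 on the log2 scale, and no pair held identical values.

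Genes were named by a fixed rule. The targeted genes came first. For each deletion the rule took the 10 highest and 10 lowest log2 fold changes among genes past the threshold that moved the same way in every clone pair, with a group mean RPKM of at least 5 in at least 1 group. For controls and differences it took 5 of each, and where no gene passed it took the 5 with the smallest p. Predicted genes, RIKEN clones, small RNAs and antisense transcripts were counted but not named. Some genes that the rule or the lists selected are not reported here; counts of genes and list values include them, and the search for single far libraries did not test them as single genes. In comparisons of single libraries or columns the rule took the 10 highest and 10 lowest log2 ratios among genes with a value of at least 5, and leaving out such symbols there was decided after the data were seen. Wapl has the older symbol Wapal in the files.

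The naming rule and the gene lists, 25 in all, were written before the data were examined, except where stated. They covered cohesin and its regulators, CTCF and related insulator factors, clustered protocadherins, Hox genes, imprinted genes, interferon response, p53 targets, cell cycle, histone genes, extracellular matrix, smooth muscle and SRF targets, immediate early genes, inflammatory genes, integrated stress response, cholesterol biosynthesis, ribosomal proteins and the respiratory chain. Markers of macrophages, endothelium, muscle, neural cells, epithelium, adipocytes, chondrocytes and osteoblasts, and fibroblasts were the remaining lists. The ribosomal list was taken by symbol and so also holds the Rps6ka kinases. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, and fry, were alternatives. For single columns, a list's median was placed among 10000 random lists of the same size matched on mean expression in 10 bins.

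The alternatives tried were other pseudocounts, filters and scalings, a model on the compared groups alone, the clone block, empirical Bayes without trend and robust options, and leaving out each library in turn. A limma test of the GRO-seq libraries had been planned. It could not be run because the columns are pooled, so GRO-seq is described without a test. The separate RPKM table holds 2 libraries with the same label, clone 3 after Adeno-Cre. The labels tell them apart only by a laboratory number, and the table's name points to serum stimulation. The lower number directly follows that of untreated clone 3, as treated numbers follow untreated ones in most other pairs of a clone. Beyond this the labels give no reason to prefer either. The one with the lower number was taken as the treated replicate of clone 3, and the one with the higher number was kept as a group of its own. It had been planned to compare the higher-numbered library with an untreated library in its table, but the table holds none, so it was compared with the lower-numbered one.

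The model, camera, the placement of neighbouring genes and the random lists were tested on simulated data, and the other steps were not. With 100 genes changed at each size among about 12000 unchanged ones, the model recovered 69% of genes at a log2 change of 1 and 90% at 2 for the Ctcf design (11996 genes). The recovered shares were 79% and 100% for Smc3 (11992 genes), 69% and 93% for Wapl (12011 genes), and 50% and 89% for Ctcf and Wapl (11988 genes), with 9 to 12 false calls per design. Simulated without any change, the Ctcf, Smc3 and Wapl designs gave 0 calls each, and the Ctcf and Wapl design gave 1. Camera called 50 of 50 shifted lists and 1 of 200 lists without a shift in the Ctcf design. Genes in the simulations of the model and of camera varied independently and without clone effects. The camera shares therefore do not cover lists whose members vary together. The changed genes and the camera lists were drawn only from genes with a mean log2(RPKM + 1) above 2. The recovered shares thus do not cover tested genes with lower values. In 20 simulations each over 12000 genes, the placement test for neighbouring genes found 20 of 20 planted patterns and 0 without one, and the matched random lists found 19 of 20 shifted lists and 0 without a shift. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.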

Results

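The RNA-seq data addressed how gene expression in quiescent fibroblasts changes when CTCF, cohesin (Smc3) or the cohesin release factor Wapl is removed. In the main table, Smc3 was represented by 4 untreated and 4 treated libraries (clone 1 with both alleles floxed, clones 2 to 4 with 1 floxed and 1 null allele), and Ctcf, Wapl, wild-type and Cre-ER cells by 2 and 2. The Wapl clones carried 1 floxed and 1 null Wapl allele, so their untreated cells already lacked 1 allele. The Ctcf clones, and the Ctcf and Wapl clones, had both alleles floxed. The Ctcf and Wapl floxed cells were represented by 2 untreated libraries, from clones 3 and 4, and 1 Adeno-Cre library, from clone 4. Untreated clone 3 had the Y-linked Eif2s3y at 5.07 RPKM and Xist at 0. Clone 4 had Eif2s3y at 0, and Xist at 3.67 RPKM untreated and 3.17 treated. Without the clone block, the treated library is thus set against untreated libraries that differ in sex-linked expression. Library depth ranged from 7.5 M reads in genes (untreated Smc3 replicate 1) to 37.8 M (untreated Ctcf replicate 1).

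Ctcf mRNA was lower wherever Ctcf had been deleted. It fell from 12.4 ± 1.19 RPKM (SD, n = 2) to 4.13 ± 0.129 (n = 2) in the Ctcf floxed cells, a log2 fold change of -1.38 (SE 0.13, limma with Benjamini-Hochberg adjustment, adjusted p = 1.69e-06). With Ctcf and Wapl deleted together it fell from 10.9 ± 2.30 RPKM (n = 2) to 3.76 (n = 1), with an adjusted p of 2.21e-05. Wapal mRNA, which encodes Wapl, fell in that library from 3.32 ± 0.846 to 1.52 RPKM (adjusted p = 0.0275, and 0.11 without the untreated library of clone 4). In Wapl floxed cells, which carried 1 null allele before treatment, Wapal stood at 1.64 ± 0.226 RPKM untreated and 0.847 ± 0.0951 treated (n = 2 each), lower in 2 of 2 clones. That difference did not pass the threshold (adjusted p = 0.167) without the clone block and did with it (adjusted p = 0.0233). Smc3 mRNA was not lower in the libraries labelled Smc3-deleted, at 11.6 ± 1.07 RPKM against 9.53 ± 1.3 untreated (n = 4 each), and was higher in 4 of 4 clones. The adjusted p was 0.119, and 0.0421 with the clone block. RPKM over a whole gene does not check the loss of some exons, so the label of the Smc3 deletion rests on the submitters alone, and every direction given below for Smc3 depends on it.

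**Figure D1:**
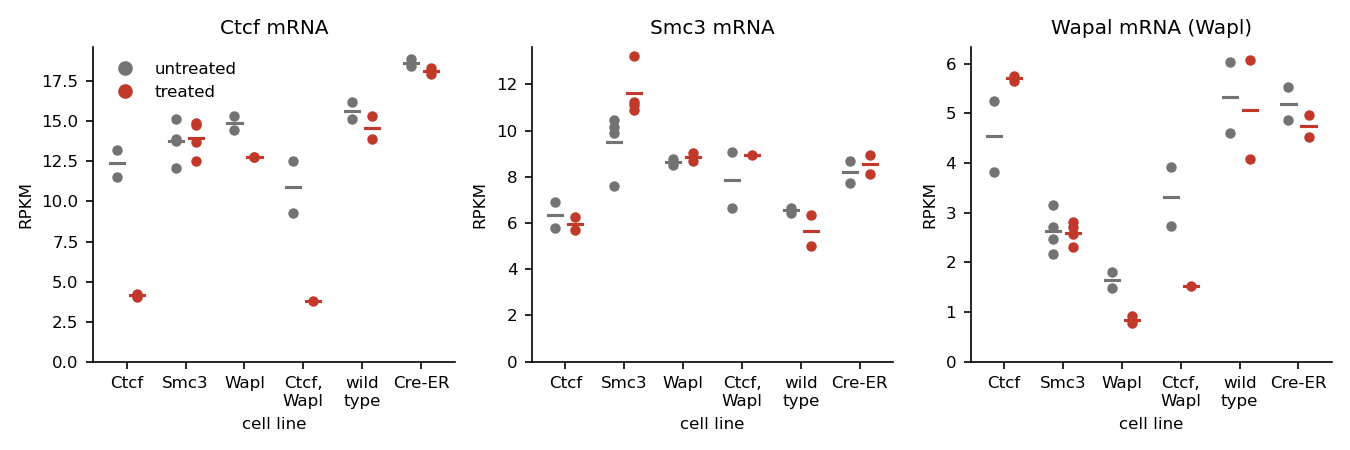
RPKM of Ctcf, Smc3 and Wapal in each RNA-seq library of the main table, by cell line, with untreated libraries in grey, treated ones in red and bars at the group means. Ctcf falls to means of 4.13 and 3.76 RPKM in the treated Ctcf and the treated Ctcf and Wapl floxed cells, and Smc3 stands at 11.6 RPKM in the treated Smc3 floxed cells.

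Adeno-Cre in wild-type cells served to show what the virus and Cre do without a floxed gene. Isg15, a ubiquitin-like protein induced by interferon, rose from 24.1 ± 3.05 to 344 ± 130 RPKM (SD, n = 2 each; log2 fold change 3.73, SE 0.69, adjusted p = 0.00781). Usp18, which removes Isg15 from proteins, the transcription factor Irf7 and the nucleic acid sensor Zbp1 rose with log2 fold changes of 2.99 to 3.24. The histone gene Hist1h4h rose from 23.1 ± 1.34 to 210 ± 58.6 RPKM (adjusted p = 2.73e-05). The proteoglycan gene Fmod fell from 193 ± 51.3 to 53.7 ± 14.2 RPKM, and Ahnak, Grb10, Mtss1 and Maf fell with log2 fold changes of -1.44 to -1.04. Maf did not pass with the clone block (adjusted p = 0.0513).

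Of 50 measured interferon response genes, 26 rose and 0 fell after Adeno-Cre in wild-type cells (46 when adjusted over the list alone, 47 with the clone block; median log2 fold change 1.54). They included Oasl1, which went from 0.264 to 6.23 RPKM, and Bst2, which went from 144 to 852 RPKM. The list passed camera (adjusted p = 9.28e-32), but not with an estimated correlation (adjusted p = 0.266). Of 33 measured histone genes, 24 rose and 0 fell (29 adjusted over the list alone), and this list also passed with an estimated correlation (adjusted p = 0.000745). Hist1h4a, Hist1h4j and Hist1h1e were among them. Histone genes are near-identical copies of each other and most of their transcripts lack a poly(A) tail, so single members are uncertain. Respiratory chain genes rose in 11 of 88 cases (34 adjusted over the list alone, 61 with the block; Ndufs7, Cox4i1, Ndufb6 and Ndufb9 among them), with an adjusted p of 0.392 with an estimated correlation, and their median went from 0.55 to 0.11 with the length trend of each library removed. Ribosomal protein genes rose in 3 of 90 cases (4 adjusted over the list alone, 34 with the block; median 0.44, and -0.04 with the length trend removed; adjusted p = 0.535 with an estimated correlation): Rpl41, Rps10 and Rpl24. The protocadherin and extracellular matrix lists passed camera in the lower direction with medians of -0.32 and -0.26, with 0 and 1 members past the threshold, 0 and 1 adjusted over the list alone and 2 and 8 with the block. Their adjusted p-values were 0.392 and 0.358 with an estimated correlation. In all, 340 genes were higher and 68 lower, 83.3% higher against 70% (194 and 83) after median-of-ratios rescaling, and 89 and 29 passed with the length trend removed. With the clone block the counts were 1987 and 912, and the total of 408 changed to 63 without untreated wild-type replicate 1, 41 without treated replicate 1 and 65 without untreated replicate 2.

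Hydroxytamoxifen in Cre-ER cells, the control for the Smc3 and Wapl deletions, gave no called gene. The smallest p-values belonged to Hoxb13 (0.314 RPKM treated and 1.03 untreated), Cenph, Rpl41, Hmx1 and Mutyh, all with an adjusted p of 1. The count of genes past the threshold was 0, with 41 at an unadjusted limma p under 0.05, and 0 and 187 with the clone block. The count was 2 without untreated Cre-ER replicate 4. No gene list passed camera. The lowest list median was that of macrophage markers, at -0.51 (camera adjusted p = 0.0722), and that list passed with the clone block (adjusted p = 0.00404), as did the chondrocyte and osteoblast list in the higher direction (median 0.17, camera adjusted p = 0.0545, and 0.00406 with the block).

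**Figure D2:**
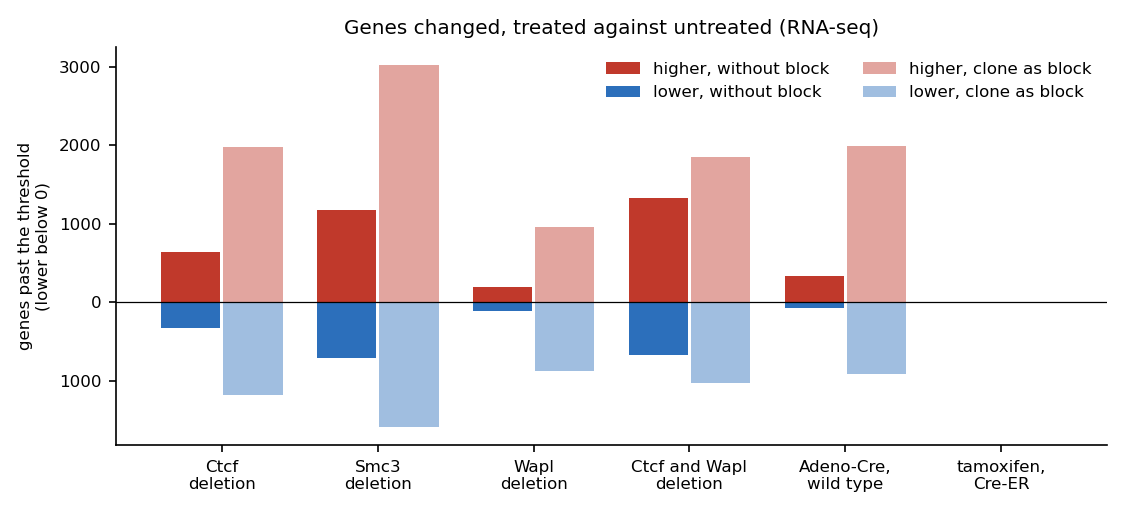
Number of genes past the threshold in each RNA-seq comparison of treated with untreated libraries, with higher genes above 0 in red and lower genes below 0 in blue. Dark bars are counts without and pale bars counts with the clone as a block, which raises the total from 966 to 3155 for Ctcf and from 306 to 1839 for Wapl.

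After deletion of Ctcf, clustered protocadherins fell. Among other genes, Cldn3, a tight junction protein of epithelia, rose from 0.286 ± 0.104 to 24.6 ± 3.57 RPKM (SD, n = 2 each; log2 fold change 4.31, SE 0.22, adjusted p = 8.26e-10). Ada, which encodes adenosine deaminase, rose from 7.09 ± 0.577 to 88.6 ± 1.11 RPKM (adjusted p = 2.55e-05), and Tubb3, a tubulin typical of neurons, rose from 19.1 ± 4.39 to 152 ± 8.30 RPKM (adjusted p = 1.2e-05). Agt, Svip, Gldc (glycine decarboxylase), Slc14a1 (a urea transporter), Bdh1, Pip5k1b and Fabp3 rose with log2 fold changes of 2.45 to 2.92. Agt was uneven, at 25.9 ± 28.5 RPKM treated, with log2 fold changes of 1.87 and 3.97 in the 2 clones. In the other direction Fmod fell from 252 ± 9.96 to 27.0 ± 7.88 RPKM (log2 fold change -3.20, SE 0.32, adjusted p = 3.76e-06), and Prelp, another small proteoglycan of the matrix, fell from 536 ± 26.3 to 96.3 ± 21.7 RPKM. Fmod also fell with Adeno-Cre alone in wild-type cells (log2 fold change -1.82). Fmo2, Cxcr7, Thsd4, Ehd2, C1ra, Dio3 and Ppap2b fell with log2 fold changes of -2.67 to -2.07.

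Of 33 measured clustered protocadherins, cell adhesion genes transcribed from alternative promoters in 3 arrays, 26 fell and 0 rose after Ctcf deletion (29 adjusted over the list alone; median log2 fold change -0.88). Pcdhga2 went from 4.10 to 0.640 RPKM and Pcdhb22 from 5.85 to 0.998 RPKM. By array, 9 of 11 Pcdhb and 17 of 21 Pcdhg genes fell, and the 1 measured Pcdha gene, Pcdhac2, had a log2 fold change of 0.50. The list passed camera at 1.59e-27 and with an estimated correlation (adjusted p = 0.016). The Pcdhg transcripts share their last exons, so single Pcdhg values are uncertain. With Adeno-Cre alone in wild-type cells the Pcdhb and Pcdhg medians were -0.30 and -0.35, with 0 genes past the threshold. Part of the fall may therefore not be due to loss of Ctcf. Histone genes rose in 17 of 33 cases (23 adjusted over the list alone; Hist1h4h from 26.5 to 126 RPKM) and also passed with an estimated correlation (adjusted p = 0.0139), but Adeno-Cre alone raised 24 of 33 in wild-type cells, so this rise cannot be assigned to loss of Ctcf. The other lists that passed camera did not pass with an estimated correlation. Extracellular matrix genes fell in 6 of 47 cases and rose in 1 (the same counts adjusted over the list alone, 13 and 6 with the clone block; adjusted p = 0.203 with an estimated correlation), with Mmp14 and Timp2 among the lower ones. Respiratory chain genes rose in 9 of 88 cases (16 adjusted over the list alone, 43 with the block; adjusted p = 0.847 with an estimated correlation), among them Atp5o, Atp5b and Cox6b2, and 1 fell, Ndufaf3, from 19.4 to 5.06 RPKM. Cell cycle genes had a median of 0.35, with 1 risen (Mcm2), 0 adjusted over the list alone and 4 with the block (adjusted p = 0.936 with an estimated correlation). Hox genes had a median of -0.21, with 1 risen (Hoxc13, from 2.35 to 6.91 RPKM, also 1 adjusted over the list alone, with 7 lower in addition under the block; adjusted p = 0.565 with an estimated correlation). Immediate early genes had a median of -0.71 with 0 past the threshold, also adjusted over the list alone, and 14 lower with the block (adjusted p = 0.966 with an estimated correlation, and 0.0854 by camera after median-of-ratios rescaling).

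After Ctcf deletion 635 genes were higher and 331 lower, 65.7% higher against 55.5% (521 and 418) after median-of-ratios rescaling. With the clone block the counts were 1977 and 1178, and the total of 966 changed to 379 without untreated Ctcf replicate 1, 599 without treated replicate 1 and 487 without treated replicate 2. Set against Adeno-Cre in wild-type cells, 184 genes differed in their change, 93 higher and 91 lower (431 and 445 with the block). Cldn3, Ada, Slc14a1, Pip5k1b and Bdh1 differed by 2.48 to 3.55 on the log2 scale. Ifit1, Zbp1, Irf7, Krtcap2 and H2-T23 differed by -3.42 to -2.46, and Ifit1, for instance, had a log2 fold change of -0.93 in Ctcf floxed and 2.49 in wild-type cells (adjusted p of the difference 0.0202). The interferon list differed in the lower direction with 6 of 50 genes past the threshold (42 adjusted over the list alone, 28 with the block; median -1.65), and the protocadherins with 2 of 33 (11 adjusted over the list alone, 8 with the block; median -0.56), both with an adjusted p of 0.202 with an estimated correlation. Hox, histone, inflammatory, ribosomal and respiratory chain genes also passed camera in the lower direction, with at most 1 gene past the threshold each, also adjusted over the list alone, and an adjusted p of 0.435 to 0.915 with an estimated correlation, and histones did not pass with the block (adjusted p = 0.122). The count of 184 was 116, 109 and 106 without untreated replicate 1, treated replicate 1 and untreated replicate 2 of the wild-type cells, and 97 without treated Ctcf replicate 1.

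**Figure D3:**
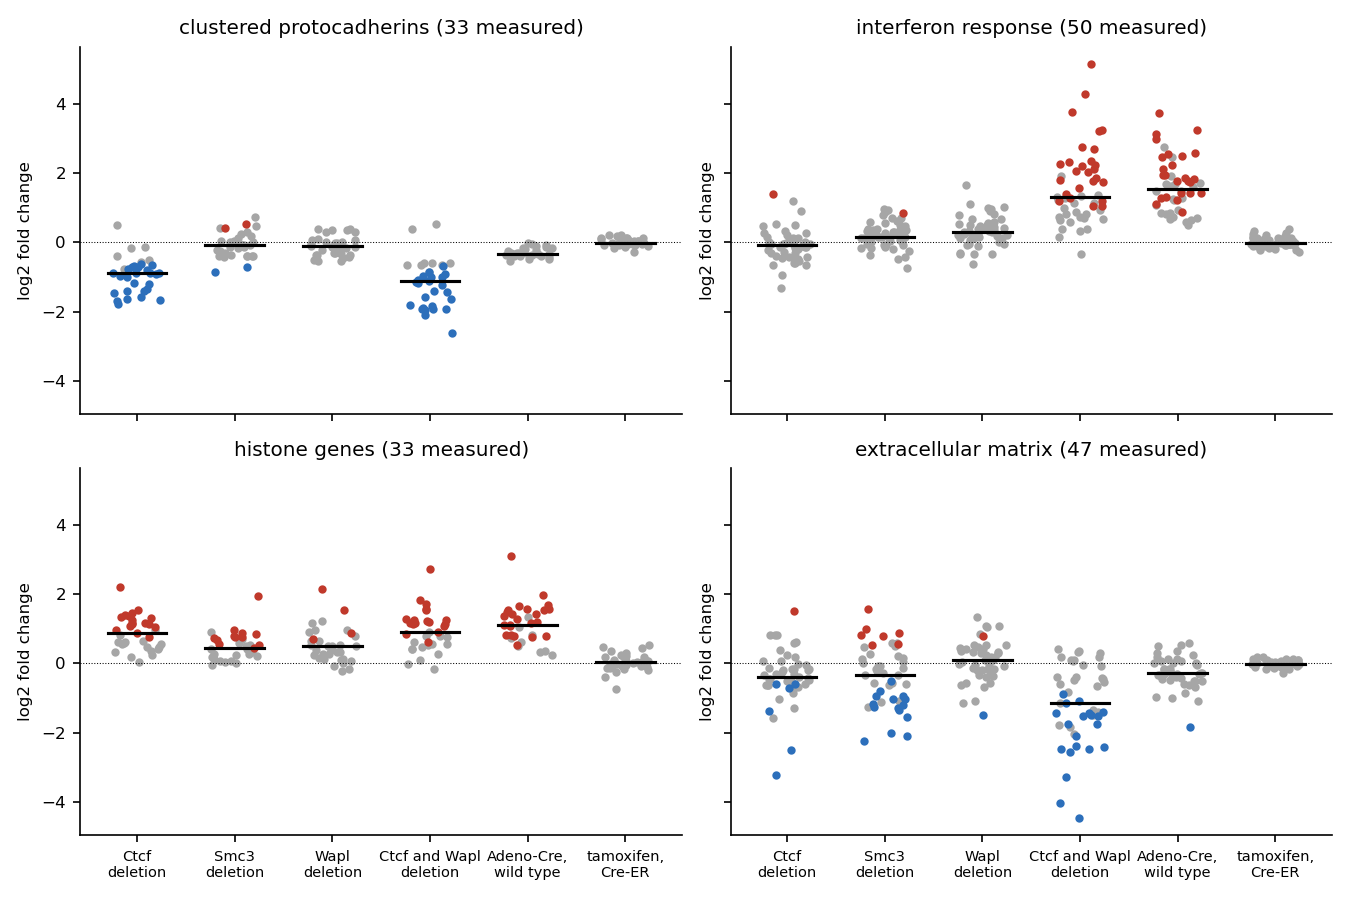
Log2 fold change of each measured member of 4 gene lists in the 6 RNA-seq comparisons, with members past the threshold in red (higher) or blue (lower), other members in grey and a bar at the median. Clustered protocadherins have medians of -0.88 and -1.12 in the 2 deletions that include Ctcf, and interferon response genes have medians of 1.54 and 1.29 after Adeno-Cre in wild-type and in Ctcf and Wapl floxed cells.

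In the libraries labelled Smc3-deleted H19, an imprinted noncoding RNA, fell from 1157 ± 526 to 49.4 ± 70.1 RPKM (SD, n = 4 each; log2 fold change -5.84, SE 0.81, adjusted p = 0.000119). Penk (proenkephalin) fell from 350 ± 383 to 5.38 ± 4.50 RPKM, Sfrp2, a secreted Wnt antagonist, from 461 ± 283 to 17.6 ± 14.2 RPKM, and the chemokine gene Cxcl12 from 92.1 ± 42.7 to 7.68 ± 5.07 RPKM, each in 4 of 4 clones. Reg1, Crabp1, Lgr5, Cthrc1, Cxcl14 and Gdf10 fell with log2 fold changes of -3.91 to -3.42. Aard rose from 2.56 ± 0.327 to 29.4 ± 15.5 RPKM (log2 fold change 2.96, SE 0.33, adjusted p = 1.49e-05), and Tnnt2, cardiac troponin T, from 2.54 ± 0.866 to 28.7 ± 25.7 RPKM. Inmt, Aass, Nnat, Clca1, Apcdd1 and Trp53i11 rose with log2 fold changes of 2.02 to 2.44. Inmt was uneven, at 10.1 ± 10.1 RPKM treated, with log2 fold changes from 0.33 to 4.03 over the 4 clones.

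In the libraries labelled Smc3-deleted, extracellular matrix genes fell in 15 of 47 cases and rose in 7 (20 and 7 adjusted over the list alone, 23 and 10 with the clone block). Fmod, Thbs1 and Fbln1 were lower, and Nid1 was higher, at 330 against 164 RPKM. Histone genes rose in 12 of 33 cases (16 adjusted over the list alone; Hist1h4h, Hist1h1e, Hist1h2bc and Hist3h2a). Integrated stress response genes fell in 7 of 26 cases and rose in 1 (9 and 1 adjusted over the list alone, 13 and 1 with the block), and the lower ones included the amino acid transporter genes Slc7a5 and Slc3a2, Vldlr and Cebpb. Adipocyte markers fell in 5 of 13 cases (8 adjusted over the list alone, 9 with the block), among them Pparg, Fabp4, Cebpa and Dgat2. Muscle markers rose in 6 of 14 cases (8 adjusted over the list alone), among them Myh1, Myh8, Tnnt2 and Tnnc1. These 5 lists each had an adjusted p of 0.143 with an estimated correlation. Cholesterol biosynthesis genes rose in 6 of 23 cases (10 adjusted over the list alone, 15 with the block; Tm7sf2, Hsd17b7 and Pmvk among them; adjusted p = 0.570 with an estimated correlation). Inflammatory genes fell in 5 of 27 cases (5 lower and 1 higher adjusted over the list alone, 11 and 2 with the block; Cxcl12, Saa3, Mmp3 and Lcn2; adjusted p = 0.190 with an estimated correlation). Ribosomal protein genes fell in 9 of 90 cases (6 adjusted over the list alone, 29 with the block; adjusted p = 0.377 with an estimated correlation); Rpl12 and Rplp0 were among them, as was the kinase gene Rps6ka5. Myc, of the immediate early genes, fell from 38.1 to 5.44 RPKM, the only member of 24 past the threshold, also adjusted over the list alone, against 18 with the block (list adjusted p = 0.637 with an estimated correlation).

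Markers of other cell types moved in the same libraries. Macrophage markers had a median log2 fold change of -1.62 in the libraries labelled Smc3-deleted, with 0 of 18 past the threshold, also adjusted over the list alone, and 13 lower with the clone block (adjusted p = 0.584 with an estimated correlation). Ctss stood at 5.10 against 44.1 RPKM untreated and Emr1 at 0.605 against 7.94 RPKM (adjusted p = 0.00431 and 0.0229 with the block). Endothelial markers fell in 2 of 8 cases, also adjusted over the list alone, and in 5 with the block (Flt1 and Egfl7; adjusted p = 0.122 with an estimated correlation). Neural markers fell in 3 of 14 cases and rose in 1, also adjusted over the list alone: Ncam1 and Foxd3 fell and Tubb3 rose (adjusted p = 0.442 with an estimated correlation). Protocadherins passed camera in the lower direction with a median of -0.09, 2 risen (Pcdhb18 and Pcdhb16) and 2 fallen (Pcdhgb7 and Pcdhga12), also adjusted over the list alone, and 5 and 8 with the block (adjusted p = 0.637 with an estimated correlation, and 0.0657 by camera after median-of-ratios rescaling).

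In all, 1181 genes were higher and 706 lower in the libraries labelled Smc3-deleted, 62.6% higher against 52.6% (882 and 795) after median-of-ratios rescaling. With the clone block the counts were 3025 and 1591. Set against hydroxytamoxifen in Cre-ER cells, 155 genes differed in their change, 59 higher and 96 lower, 38.1% higher against 25.7% (36 and 104) after median-of-ratios rescaling and 800 and 543 genes with the block. Aard, Hist1h4h, Nnat, Aass and Trp53i11 differed by 1.92 to 2.93 on the log2 scale, and Sfrp2, Lgr5, Cthrc1, Saa3 and Crabp1 by -5.07 to -3.58. Nnat did not pass after median-of-ratios rescaling. Of the lists, adipocyte markers differed with a median of -1.25, with 0 of 13 genes past the threshold (5 adjusted over the list alone, 3 with the block; adjusted p = 0.133 with an estimated correlation). Muscle markers differed with a median of 0.56 (2 of 14 genes higher, 5 adjusted over the list alone, 4 with the block; adjusted p = 0.133 with an estimated correlation). Cholesterol biosynthesis genes and macrophage markers differed with medians of 0.60 and -1.17, with 0 genes past the threshold in either, also adjusted over the list alone or with the block (adjusted p = 0.735 with an estimated correlation for both). The count of 155 was 30, 21, 37 and 33 without untreated and treated Cre-ER replicates 3 and 4 in turn, and 284, 85 and 79 without treated Smc3 replicates 1, 3 and 4.

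After deletion of Wapl Nxph4, a secreted ligand of neurexins, rose from 1.21 ± 0.585 to 28.4 ± 2.23 RPKM (SD, n = 2 each; log2 fold change 3.76, SE 0.27, adjusted p = 9.87e-08). Grm4, a glutamate receptor, rose from 0.0815 ± 0.115 to 6.74 ± 0.408 RPKM (adjusted p = 1.55e-11), and Ache, which encodes acetylcholinesterase, rose from 0.252 ± 0.114 to 6.43 ± 1.15 RPKM (adjusted p = 3.12e-08). Ccl11, Hist1h4h, Rasgrp2, Aass, Cdh26, Cntfr and Ntf3 rose with log2 fold changes of 1.84 to 2.38. Gfra2, a receptor of the GDNF family, fell from 11.1 ± 2.85 to 2.67 ± 0.0614 RPKM (log2 fold change -1.71, SE 0.42, adjusted p = 0.0379), and Pparg, Ak5, Fmod, Snhg12, Angptl1, Sox4, Mgll, Marcksl1 and Dact1 fell with log2 fold changes of -1.62 to -1.39. Angptl1, Sox4 and Dact1 did not pass after median-of-ratios rescaling.

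Of the lists, histone genes rose in 4 of 33 cases after Wapl deletion (9 adjusted over the list alone, 10 with the clone block; Hist1h4h, Hist1h2bj, Hist1h2bc and Hist1h1e; adjusted p = 0.117 with an estimated correlation). Cell cycle genes had a median of -0.51 with 1 fallen, the replication licensing factor gene Cdt1, from 10.5 to 3.92 RPKM (6 adjusted over the list alone, 11 with the block). Integrated stress response genes fell in 2 of 26 cases, also adjusted over the list alone (Slc3a2 and Slc7a5, 10 with the block). Ribosomal protein genes had a median of -0.32 with 0 of 90 past the threshold, also adjusted over the list alone, and 24 lower with the block. These 3 lists each had an adjusted p of 0.729 with an estimated correlation, as did Hox genes (median 0.10; 1 risen, Hoxc6, also adjusted over the list alone, and 10 with the block), which did not pass with the block (adjusted p = 0.0611). The interferon list had a median of 0.31 and the macrophage list a median of -1.23, with 0 members past the threshold in either, also adjusted over the list alone, and an adjusted p of 0.905 with an estimated correlation. Isg15 stood at 146 RPKM against 46.6 untreated and was the 1 interferon member past the threshold with the block (adjusted p = 0.0478), and Emr1 at 9.36 against 38.5.

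After Wapl deletion 189 genes were higher and 117 lower, and 960 and 879 with the clone block. The total of 306 changed to 56 without untreated replicate 1, 21 without treated replicate 1 and 79 without untreated replicate 2. Set against hydroxytamoxifen in Cre-ER cells, 18 genes differed in their change, 14 higher and 4 lower (180 and 132 with the block). Nxph4, Hist1h4h, Grm4, Ache and Rasgrp2 differed by 2.22 to 3.99 on the log2 scale and Marcksl1, Efnb2 and Pet112 by -1.52 to -1.19. Marcksl1 and Efnb2 did not pass after median-of-ratios rescaling. Histone genes differed with a median of 0.44 (1 of 33 higher, 4 adjusted over the list alone, 3 with the block; adjusted p = 0.362 with an estimated correlation), and cell cycle genes with a median of -0.42 and 0 of 33 past the threshold, also adjusted over the list alone (adjusted p = 0.819 with an estimated correlation). The count of 18 fell in each case when 1 library was left out: to 6, 9, 11 and 9 without the 4 Cre-ER libraries and to 11, 4, 9 and 11 without the 4 Wapl libraries.

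Deletion of Ctcf and Wapl together was measured in 1 treated library of clone 4 against 2 untreated ones. Its p-values and list tests assume that this library varies like the other groups, and 24 genes passed on the 2 groups alone against 1997. Isg15 rose from 8.71 ± 2.39 RPKM (SD, n = 2) to 338 (n = 1; log2 fold change 5.15, SE 0.85, adjusted p = 0.000516), and Usp18 from 1.17 ± 0.127 to 41.1 RPKM, and both also rose with Adeno-Cre alone in wild-type cells, Isg15 to 344 RPKM. The tight junction genes Cldn4 and Cldn3 rose from 0.218 ± 0.224 to 37.1 RPKM and from 0.0333 ± 0.0166 to 16.2 RPKM (adjusted p = 8.14e-10 and 2.57e-08). Rec8, a cohesin subunit of meiotic cells, rose from 0.0831 ± 0.0798 to 24.4 RPKM (adjusted p = 2.36e-08), and Crct1, Nefm, Acta1, Sprr1a and Nxph4 rose with log2 fold changes of 3.79 to 4.60. Eln, which encodes elastin, fell from 226 ± 71.3 to 9.02 RPKM (log2 fold change -4.46, SE 0.77, adjusted p = 0.000692) and Ehd2, a protein of caveolae, from 191 ± 60.3 to 8.42 RPKM. Pcsk6, Fmod, Itga11, Cxcr7 and Itga8 fell with log2 fold changes of -4.19 to -3.51. Fmod also fell with Adeno-Cre alone in wild-type cells (log2 fold change -1.82). Serping1, Pgm5 and Sfrp2 fell with log2 fold changes of -3.89, -3.68 and -3.56, which were -2.55, -3.08 and -2.37 without the untreated library of clone 3 and -5.24, -4.28 and -4.75 without that of clone 4. Without the untreated library of clone 3 Sfrp2 and Sprr1a did not pass (adjusted p = 0.226 and 0.0717), and Sfrp2 did not pass with the clone block (adjusted p = 0.107).

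Of 47 extracellular matrix genes, 20 fell and 0 rose after deletion of Ctcf and Wapl (25 adjusted over the list alone; median -1.15), among them Lox, from 1710 to 306 RPKM, and Prelp, from 243 to 18.7 RPKM. The list passed with an estimated correlation (adjusted p = 0.00519). So did the protocadherins (adjusted p = 0.0228), of which 24 of 33 fell and 0 rose (30 adjusted over the list alone; median -1.12), 5 of 11 Pcdhb and 19 of 21 Pcdhg genes. Pcdhga7 went from 7.45 to 0.362 RPKM. Adeno-Cre alone in wild-type cells gave Pcdhb and Pcdhg medians of -0.30 and -0.35. Interferon response genes rose in 26 of 50 cases and fell in 0 (37 adjusted over the list alone; median 1.29), with Oasl1, Bst2 and Ifi44 among them (adjusted p = 0.474 with an estimated correlation). Histone genes rose in 18 of 33 cases (21 adjusted over the list alone; adjusted p = 0.0801 with an estimated correlation). Adeno-Cre alone raised 26 and 24 genes of these 2 lists in wild-type cells, so neither rise can be assigned to the deletion. Cholesterol biosynthesis genes fell in 9 of 23 cases (15 adjusted over the list alone; Insig1, Srebf2 and Dhcr7 among them; adjusted p = 0.381 with an estimated correlation). Ribosomal protein genes had a median of -0.19, with Rplp0 and Rpl36a lower and the kinase gene Rps6ka2 higher, also adjusted over the list alone (adjusted p = 0.541 with an estimated correlation). Hox genes fell in 3 of 38 cases and rose in 1, also adjusted over the list alone (Hoxb3, Hoxb8 and Hoxb2 lower, Hoxc13 higher, and 11 lower and 3 higher with the clone block; adjusted p = 0.381 with an estimated correlation). Of the cell type lists, fibroblast markers fell in 4 of 20 cases (9 adjusted over the list alone, 7 lower and 2 higher with the block; Pdgfrb, Mfap5, Col1a2 and Pdgfra, the last not past the threshold with the block; adjusted p = 0.244 with an estimated correlation). Epithelial markers rose in 5 of 11 cases, also adjusted over the list alone (Cldn4, Cldn3, Dsp and Krt19 among them; adjusted p = 0.474 with an estimated correlation and 0.0656 with the block).

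In all, 1324 genes were higher and 673 lower, 66.3% higher against 42.6% (685 and 924) after median-of-ratios rescaling, which moved the median log2 fold change of all genes from 0.18 to -0.00. With the length trend of each library removed 808 genes were higher and 1010 lower. The total of 1997 changed to 1060 without the untreated library of clone 3. The lower-numbered treated library of clone 3 stood in a separately normalized table and entered no test. Of the 1847 genes called higher with the clone block, which compares libraries of clone 4, 1774 (96.0%) were also higher in this library than in untreated clone 3, and of 1030 called lower 983 (95.4%) were lower. In the higher-numbered library, which carries the same label, 808 (43.7%) were higher and 720 (69.9%) lower. Ctcf stood at 7.61 RPKM in it against 3.17. Its Y-linked genes and Xist differed from untreated clone 3 by -1.71 and 0.99 on the log2 scale. These sex-linked values argue against clone 3 as its source, so its shares may compare different clones. The log2 ratios of the lower-numbered library and of clone 4 correlated across 12604 genes at 0.77, set across these tables.

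Set against Adeno-Cre in wild-type cells, 488 genes differed in their change after deletion of Ctcf and Wapl, 217 of them lower (789 and 726 with the clone block), 55.5% higher against 42.4% (193 and 262) after median-of-ratios rescaling. Cldn4, Nefm, Rec8, Slc29a4 and Crabp2 differed by 3.36 to 4.94 on the log2 scale and Crabp1, Ehd2, Galntl4, Krtcap2 and Adra1d by -5.06 to -3.70. Crabp2 did not pass after median-of-ratios rescaling. Protocadherins differed with a median of -0.82 (9 of 33 lower, 18 lower and 1 higher adjusted over the list alone; adjusted p = 0.126 with an estimated correlation) and extracellular matrix genes with a median of -0.72 (4 of 47 lower, 13 adjusted over the list alone, 14 with the block; adjusted p = 0.0566 with an estimated correlation). The count of 488 was 303, 261 and 285 without untreated replicate 1, treated replicate 1 and untreated replicate 2 of the wild-type cells, and 270 and 1153 without the untreated libraries of clones 3 and 4.

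Set against Ctcf deletion alone, which used other clones, 174 genes differed, 98 higher and 76 lower (318 and 314 with the clone block), 56.3% higher against 39.9% (63 and 95) after median-of-ratios rescaling. Isg15, Crct1, Cldn4, Tgfbi and Mmp10 differed by 3.62 to 4.67 on the log2 scale and Pcsk6, Crabp1, Adamts2, Sncaip and Adra1d by -4.08 to -3.06. Crabp1 did not pass with the block (adjusted p = 0.0629) or after median-of-ratios rescaling. Interferon response genes differed with a median of 1.33 (6 of 50 higher, 23 adjusted over the list alone, 13 with the block; adjusted p = 0.356 with an estimated correlation). Extracellular matrix genes differed with a median of -0.73 (2 of 47 lower, 11 lower and 2 higher adjusted over the list alone, 8 lower with the block) and passed with an estimated correlation (adjusted p = 0.0426). The protocadherin list passed camera with a median of -0.27 and 0 genes past the threshold, also adjusted over the list alone, and did not pass with the block (adjusted p = 0.386) or after median-of-ratios rescaling (adjusted p = 0.0529). The count of 174 was 90, 97 and 74 without untreated replicate 1, treated replicate 1 and treated replicate 2 of the Ctcf cells, and 83 and 581 without the untreated libraries of clones 3 and 4.

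Ctcf deletion and the libraries labelled Smc3-deleted differed in the change of 889 genes, 452 higher and 437 lower after Ctcf deletion (1492 and 1548 with the clone block). This difference also sets Adeno-Cre, which alone changed 408 genes, against hydroxytamoxifen, so it cannot be assigned to the deleted genes alone. Cldn3, Crabp1, Ada, Fxyd5 and Cthrc1 differed by 3.43 to 4.38 on the log2 scale, and Fgl2, Tnnt2, Prelp and Man2b2 by -3.92 to -2.52. Crabp1 had a log2 fold change of 0.42 after Ctcf deletion and -3.90 in the libraries labelled Smc3-deleted. Protocadherins differed in 14 of 33 cases, all lower after Ctcf deletion (21 adjusted over the list alone; adjusted p = 0.258 with an estimated correlation). The count of 889 was 410, 534 and 520 without untreated replicate 1, treated replicate 1 and treated replicate 2 of the Ctcf cells.

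Across 12604 genes, the log2 fold changes of Ctcf deletion and of deletion of Ctcf and Wapl correlated at 0.56 (Pearson; Spearman 0.48), the highest Pearson value of the 15 pairs of RNA-seq comparisons. They had 328 higher and 230 lower genes in common, against 66.7 and 17.7 from lists placed independently. Smc3 and Wapl correlated at 0.52 (Spearman 0.45), with 88 higher and 33 lower genes in common against 17.7 and 6.6. Ctcf and Smc3 correlated at 0.28 (Spearman 0.18), and Ctcf and Wapl at 0.14 (Spearman 0.06). Adeno-Cre in wild-type cells correlated at 0.43 with Ctcf deletion (Spearman 0.48), with 123 higher and 25 lower genes in common against 17.1 and 1.8, and at 0.34 with deletion of Ctcf and Wapl (Spearman 0.31), with 149 and 22 against 35.7 and 3.6. Fold changes after Adeno-Cre in wild-type cells fell with gene length (Spearman -0.54). These correlations and overlaps were not repeated with the length trend removed, so a length bias common to the libraries may add to them. No 2 comparisons shared a library, and genes are not independent replicates, so no p is given.

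Of 14 measured genes for cohesin and its regulators, Stag1 rose in 3 deletions: from 4.14 to 7.48 RPKM after Ctcf deletion (adjusted p = 0.0192), from 5.04 to 10.3 RPKM in the libraries labelled Smc3-deleted (adjusted p = 1.2e-04), and from 4.10 to 14.6 RPKM after deletion of Ctcf and Wapl (adjusted p = 8.13e-05). Rec8 rose after Ctcf deletion from 0.0479 to 1.25 RPKM (adjusted p = 0.0178), a log2 fold change of 0.99 against 0.79 with Adeno-Cre alone in wild-type cells, so this rise cannot be assigned to loss of Ctcf. Stag2 rose and Pds5b fell in the libraries labelled Smc3-deleted, from 4.35 to 6.16 RPKM and from 2.22 to 1.29 RPKM. Rad21, Smc1a, Smc3, Nipbl, Mau2, Pds5a, Hdac8, Pttg1 and Cdca5 passed the threshold in none of the 6 RNA-seq comparisons without the clone block. With it Smc3, Nipbl and Pttg1 passed in the libraries labelled Smc3-deleted (adjusted p = 0.0421, 0.01 and 0.00681, higher in 4 of 4 clones), and Rec8 passed after Adeno-Cre in wild-type cells (adjusted p = 0.0189). The cohesin list, the CTCF and insulator list, p53 targets and smooth muscle genes did not pass camera in any of the 6, with list adjusted p-values of 0.149, 0.0812, 0.208 and 0.395 at the lowest.

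GRO-seq asked whether the changes after deletion of Ctcf and Wapl were seen in nascent RNA, in clones 1 and 2, while RNA-seq used clones 3 and 4. The columns pool 2 libraries each, so values are the authors' with no spread and no test, and ratios are on the log2(TPM + 1) scale. Mt1, a metallothionein gene, stood at 1786 TPM after Adeno-Cre and 76.1 untreated, and Crct1 at 26.9 and 0.653 TPM. Cldn3, Cldn4, Nkx2-4, Phlda2 and Ccno stood at 9.07 to 17.5 TPM after Adeno-Cre and were listed at 0 untreated. Gpatch4, Hrct1 and Duoxa2 were the other named genes on the higher side. The chemokine gene Cxcl12 stood at 4.63 against 70.9 TPM and its receptor gene Cxcr7 at 1.26 against 24.2 TPM, and Krtcap2, Lbh, Spry1 and Galntl4 had log2 ratios of -3.46 to -3.22. Rprl3, Npff, Lenep and H19 were listed at 0 after Adeno-Cre. Ctcf stood at 5.94 against 9.83 TPM and Wapal at 8.10 against 16.1 TPM. Smc3, which was not targeted in these cells, stood at 3.36 against 7.98 TPM. The median log2 ratio of 9233 genes was -0.70, so the falls of Ctcf and Wapal do not check the deletion.

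In the same GRO-seq columns 22 of 22 measured protocadherins had a ratio below 0 (median log2 ratio -1.90), as had 38 of 39 extracellular matrix genes (median -1.82) and 11 of 13 fibroblast markers (median -1.49), each at percentile 0 of the random lists. Cholesterol biosynthesis genes had a median of -1.16 (percentile 0.13). Histone genes had ratios above 0 in 59 of 60 cases (median 1.03) and interferon response genes in 11 of 19 (median 0.71), both at percentile 100. Adeno-Cre alone raised genes of both lists in wild-type RNA-seq. GRO-seq had no virus control here, so neither rise can be assigned to the deletion. The median of 9233 genes with a value of at least 5 was -0.70, and 545 were higher and 2689 lower beyond 2-fold, against 1369 and 368 after median-of-ratios rescaling. Over 8352 genes the RNA-seq and GRO-seq changes correlated at 0.39 (Spearman 0.34). Of 809 genes that rose in RNA-seq 613 (75.8%) lay above the GRO-seq median of these genes (-0.72), and of 436 that fell 366 (83.9%) lay below it. Both assays compared Adeno-Cre with untreated cells, so a shared response to the virus may add to these shares.

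DRB, an inhibitor of the kinase that releases RNA polymerase II into elongation, was applied for 3.5 h to cells with Ctcf and Wapl deleted, and 1 library each was made during treatment and 1 d after its removal. Both were compared with the pooled Adeno-Cre column, without a test. The labels give no clone for either library, so a difference between clones cannot be told apart from an effect of DRB. Histone and matrix transcripts took a smaller share of nascent RNA in the DRB library. Hist1h4j and Hist1h4k stood at 1172 and 1158 TPM without DRB and were listed at 0 in it, as were Ctrc, Hist1h2bl, Hist1h2ah and Hist1h2ba. Orai2 stood at 1.62 against 493 TPM, and Hist1h2bk, Hist2h3c1 and Hist1h2af had log2 ratios of -6.75 to -6.05. Histone genes had a median log2 ratio of -2.12, extracellular matrix genes -1.68, smooth muscle and SRF targets -2.06 and fibroblast markers -2.12, each at percentile 0. Rpl34 stood at 786 TPM in DRB against 17.0, Bola2 at 195 against 5.83, and H2-Ke2, Rnf5, Rnaseh2c, Syngr2, Cyb561d2, Sf3b5, Alkbh6 and Ssr2 had log2 ratios of 3.53 to 4.70. Respiratory chain genes had a median of 1.4 (percentile 100) and ribosomal protein genes 1.38 (percentile 99.98). Of 6854 genes, 1462 were higher and 1648 lower beyond 2-fold, against 3248 and 844 after median-of-ratios rescaling.

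At 1 d after removal of DRB, histone genes had a median log2 ratio of -1.51 (percentile 0), with Hist1h4j at 3.30 and Hist1h4k at 3.30 TPM. Ctrc stood at 0.169 against 681 TPM and Orai2 at 2.37 against 493. Hist1h2ba, Ifnz and Olfr613 were listed at 0, and Zfp488, Hist1h2ah and Hist1h2bk had log2 ratios of -5.75 to -5.15. Matrix genes had a median of 0.09, against a median of 0.22 for all 6996 genes, and smooth muscle genes a median of 0.28 (percentiles 3.13 and 23.15). Ribosomal protein genes had a median of 0.88 (percentile 100), with Rpl34 at 161 TPM. Bola2, Cbx8, H2-Ke2, Cyb561d2, Arl4d, Rpl7, Mea1, Tor1b and Rnaseh2c had log2 ratios of 2.19 to 2.95. Beyond 2-fold 580 genes were higher and 450 lower. These ratios share their denominator with those in DRB, so a gene that is high in that column by chance is low in both. A difference between clones cannot be told apart here either.

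Of the 2 libraries labelled as Ctcf and Wapl floxed clone 3 after Adeno-Cre, in a table whose name points to serum stimulation, the higher-numbered one was kept apart and compared with the lower-numbered one. The targeted genes were higher in it: Ctcf stood at 7.61 RPKM against 3.17 in the lower-numbered library and Wapal at 2.09 against 0.902. Gjb2 (a connexin), H19, Wnt2, Inhba, Tgm2, Rgs16, Dlk1, Hbegf, Upk1b and Reg1 were higher, with log2 ratios of 4.66 to 6.80, and H19 stood at 1017 against 26.3 RPKM. Isg15 stood at 3.95 against 325 RPKM, Nxph4 at 2.16 against 152 and Cldn3 at 0.454 against 63.4, and Hist1h4h, Ms4a4d, Irf7, Slc29a4, H2-Aa and Usp18 had log2 ratios of -4.72 to -4.05. Rec8 stood at 15.3 RPKM in the lower-numbered library and was listed at 0 in the higher-numbered library. The inflammatory list had a median log2 ratio of 1.60, extracellular matrix genes 1.06 and immediate early genes 1.04 (each at percentile 100), and interferon response and histone genes had medians of -2.07 and -2.41 (each at percentile 0). Beyond 2-fold 813 of 7790 genes were higher and 1462 lower, against 1119 and 968 after median-of-ratios rescaling, and the difference has no replicate check.

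**Figure D4:**
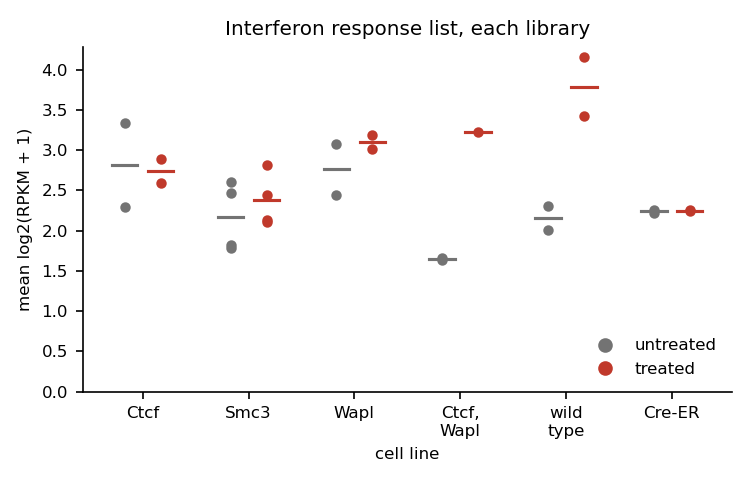
Mean log2(RPKM + 1) of the measured interferon response genes in each RNA-seq library of the main table, by cell line, with untreated libraries in grey, treated ones in red and bars at the group means. Wild-type libraries move from 2.31 and 2.01 to 4.15 and 3.42 after Adeno-Cre, while untreated Ctcf floxed libraries stand at 3.34 and 2.29.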

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

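The tests of scaling, of the respiratory chain list, of the loss of Ctcf and of the higher-numbered clone 3 library were chosen only after the results they address were seen, as was the removal of the length trend as a setting.

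After Adeno-Cre in wild-type cells 83.3% of the 408 called genes were higher, from 66.5% to 92.7% when each library was left out in turn. The fold changes fell with gene length (Spearman -0.54 over 12595 genes, 99.9% of those tested). With the length trend of each library removed, 118 genes passed and 75.4% of them were higher, and after median-of-ratios rescaling 70% were higher, so neither length nor scaling accounted for the whole excess. Length may account for 1 part: the median of the respiratory chain list went from 0.55 to 0.11 and that of the ribosomal list from 0.44 to -0.04, while histone genes went from 1.12 to 0.64 and interferon response genes from 1.54 to 1.34. A response to virus or Cre stays open for the remainder, since no library separates these.

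Interferon response genes rose with Adeno-Cre in wild-type cells and with deletion of Ctcf and Wapl, and not with Ctcf deletion (difference from Adeno-Cre, camera adjusted p = 1.23e-35, and 0.202 with an estimated correlation). After deletion of Ctcf and Wapl, medians of 1.37 in clone 4 and 1.15 in the lower-numbered library of clone 3 argue against loss of Ctcf as a bar to the rise. In these cells Wapl was deleted too, so the question stays open for loss of Ctcf with Wapl intact. The equally labelled higher-numbered library had -0.25 (set across tables). Ctcf stood at 7.61 RPKM in it, against 3.17 in the lower-numbered library and 9.26 in untreated clone 3. It therefore cannot show whether the list rises without Ctcf. A raised level before treatment could hide a rise, but the libraries do not decide it. The list mean of a treated wild-type library exceeded that of an untreated Ctcf library by as little as 0.0825 and as much as 1.86, with an average of 0.97. Untreated Ctcf replicate 1 stood at 3.34 and went to 2.59 after Adeno-Cre, and replicate 2 stood at 2.29 and went to 2.88.

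The higher-numbered library of Ctcf and Wapl floxed clone 3 departed from the lower-numbered one. Of 3 explanations, which do not exclude each other, absence of exposure and serum stay open. It may not have been exposed to virus or Cre: over 2877 called genes its change from untreated clone 3 had a slope of 0.18 on that of the lower-numbered library, and its interferon list had a median of -0.25 against untreated. The 2 changes behind that slope subtract the same untreated library, across tables, so a slope above 0 can arise without a shared response. The higher-numbered library may come from another clone: the mean of 4 Y-linked genes differed by -1.33 on the log2 scale from the lower-numbered library and by -1.71 from untreated clone 3, against at most 0.38 within 13 other clone pairs, and Xist differed by 0.99 against at most 0.31. Eif2s3y stood at 0.0162 RPKM in it, against 6.35 in the lower-numbered library and 5.07 in untreated clone 3, both with Xist at 0. Ddx3y, Kdm5d and Uty stood at 0 and Xist at 0.988 RPKM in the higher-numbered library. These values argue against clone 3 as its source, so the slope and the interferon median may compare different clones. The higher-numbered library may have been stimulated with serum: immediate early genes lay at percentile 100 of the matched random lists. Extracellular matrix, inflammatory and cholesterol biosynthesis genes did so too. The only reference was the lower-numbered library after Adeno-Cre, so the percentile cannot tell serum from absence of the deletion or virus. No biological explanation beyond these was tested.

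The Smc3 comparison, with 4 libraries in each group, was repeated over all 35 ways to split its 8 libraries. Only 1 split gave as many genes, the real one with 1887, but these splits do not keep the clone pairs. The highest other count, 1651, came from clones 1 and 3 set against clones 2 and 4, which points to a structure of the samples. Of the 8 splits that part all 4 clone pairs, the highest other gave 0, and 8 splits are too few for a share under 0.05.

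Among 94 groups of 4 values examined for a single far library, 4 exceeded the critical value for the gap over the range at 4 libraries, and chance alone gives about 1 in 20. In untreated Smc3 replicate 2 the mean of the CTCF and insulator list was 4.03 against 4.18 to 4.20 in the others (0.866). In the libraries labelled Smc3-deleted, Tnnt2 stood at 67.0 RPKM in replicate 4 against 14.0 to 19.5 (0.897), Clca1 at 65.5 in replicate 3 against 5.22 to 9.59 (0.927), and Smc3 at 13.2 in replicate 4 against 10.9 to 11.3 (0.846).

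Tests of the difference between 2 comparisons also passed for single genes. Ctcf deletion differed from Adeno-Cre in wild-type cells in 184 genes, and deletion of Ctcf and Wapl did in 488. The libraries labelled Smc3-deleted differed from hydroxytamoxifen in Cre-ER cells in 155 genes, and Wapl deletion did in 18. Ctcf deletion differed from deletion of Ctcf and Wapl in 174 genes and from the Smc3 comparison in 889.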

How the results depend on the processing

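Removal of the length trend, the crossed pairing of the Cre-ER clones, leaving out both libraries of Smc3 clone 1 and GRO-seq values as deposited were chosen only after the data were seen. The balance of higher and lower genes turned for deletion of Ctcf and Wapl after median-of-ratios rescaling (42.6% higher), with the length trend removed (808 higher and 1010 lower) and on the 2 groups alone (10 and 14). For its differences from Adeno-Cre and from Ctcf deletion it turned at both pseudocounts (171 and 253, and 22 and 42, at 0.1), at RPKM 5, after median-of-ratios rescaling (42.4% and 39.9% higher) and quantile normalization, with the length trend removed and without the untreated library of clone 3. The differences of Ctcf deletion from Adeno-Cre and from Smc3 were near even and turned under several settings, and that of Smc3 from hydroxytamoxifen turned with the clone block (800 and 543). Median-of-ratios rescaling also turned it for the higher-numbered library, for Ctcf and Wapl in GRO-seq (545 and 2689 to 1369 and 368) and for DRB (1462 and 1648 to 3248 and 844), and values as deposited did for DRB washout (67 and 1491). The 158 named genes with a test kept their direction in every setting run, and 75 also kept their side of the threshold in all. Most had been chosen from the same data for large changes past the threshold, so a kept direction was largely built in. A call was lost by 55 genes without some replicate, by 11 under a scaling alternative and by 3 with the clone block. The pseudocount of 0.1 ended 22 gene calls, that of 0.5 ended 10, and a model on the compared groups alone ended 47 of 94. Except where stated, the cause was not tested.

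The clone block raised the counts to 3155 for Ctcf, 4616 for Smc3, 1839 for Wapl and 2899 for Adeno-Cre in wild-type cells. It raised the differences to 876 (Ctcf against Adeno-Cre), 1515 (Ctcf and Wapl against Adeno-Cre), 1343 (Smc3 against hydroxytamoxifen), 312 (Wapl against hydroxytamoxifen), 632 (Ctcf and Wapl against Ctcf) and 3040 (Ctcf against Smc3). For Ctcf and Wapl it gave 2877. Among genes taken by the naming rule it brought Smc3 (0.0421) and Wapal (0.0233) past the threshold in their own deletions and took out Sfrp2 after deletion of Ctcf and Wapl (0.107), Maf after Adeno-Cre (0.0513) and Crabp1 in the difference of Ctcf and Wapl against Ctcf (0.0629). It changed no other call of a gene taken by the rule. Of list members it also brought Pttg1 (0.00681), Nipbl (0.01), Ctss (0.00431) and Emr1 (0.0229) past the threshold for Smc3, Isg15 (0.0478) for Wapl and Rec8 (0.0189) for Adeno-Cre, and took out Pdgfra (0.0939) for Ctcf and Wapl, besides members only counted in the text. It ended 12 of 100 list calls. With the Cre-ER pairing crossed the limma count for hydroxytamoxifen was 0, as it was with the pairing by label, where 187 genes had an unadjusted p under 0.05 (41 without the block).

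A model on the 2 groups alone, with fewer samples to estimate spread, gave 44 genes for Ctcf, 901 for Smc3, 2 for Wapl, 24 for Ctcf and Wapl and 4 for Adeno-Cre. With the block added it gave 2833 for Ctcf, 3123 for Smc3, 192 for Wapl and 2571 for Adeno-Cre.

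Adeno-Cre gave 265 genes at a pseudocount of 0.1, 705 without a filter, 269 after quantile normalization and 118 with the length trend removed. Hydroxytamoxifen gave 1 without a filter. Wapl against hydroxytamoxifen gave 5 at a pseudocount of 0.1, 11 at 0.5, 50 without a filter and 5 at a filter of RPKM 5. Ctcf and Wapl against Ctcf gave 64 at a pseudocount of 0.1, 719 without a filter and 57 at RPKM 5. Ctcf against Adeno-Cre gave 300 without a filter, and Ctcf and Wapl against Adeno-Cre gave 1063 without a filter and 320 at RPKM 5. Smc3 against hydroxytamoxifen gave 263 without both libraries of clone 1, left out for its other Smc3 genotype and its untreated library, the shallowest.

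An estimated correlation left 5 of 44 list calls in the deletions and controls and 1 of 56 in the differences, and fry left 27 and 15. Median-of-ratios rescaling ended 6 of 100 list calls. The correlation of Ctcf deletion with Wapl deletion was 0.17 at a pseudocount of 0.1. At RPKM 5 that of Ctcf deletion with deletion of Ctcf and Wapl was 0.58. That of the latter with Adeno-Cre was 0.32 at a pseudocount of 0.1 and 0.36 at RPKM 5. GRO-seq genes beyond 2-fold were 1737 for Ctcf and Wapl after median-of-ratios rescaling, and 1558 for DRB washout as deposited, where the lower column total is the cause.

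With each library left out in turn, the counts ranged from 379 to 744 for Ctcf, 1272 to 2063 for Smc3, 21 to 239 for Wapl, 1060 to 2854 for Ctcf and Wapl, 41 to 474 for Adeno-Cre and 0 to 2 for hydroxytamoxifen. The differences ranged from 97 to 196 (Ctcf against Adeno-Cre), 261 to 1153 (Ctcf and Wapl against Adeno-Cre), 21 to 284 (Smc3 against hydroxytamoxifen), 4 to 11 (Wapl against hydroxytamoxifen), 74 to 581 (Ctcf and Wapl against Ctcf) and 410 to 1160 (Ctcf against Smc3). A group left with 1 library was assumed to vary like the others. The only treated library of Ctcf and Wapl could not be left out. The filter, block and leave-one-out alternatives of GRO-seq were not run, as its columns are pooled. Depth limits genes near RPKM 1, which rest on as few as 22.5 reads at median length in the shallowest library.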

Other observations

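No test in this part was chosen after its result was seen. Imprinted genes are expressed from 1 parental allele. In the libraries labelled Smc3-deleted 7 of 29 fell and 2 rose (8 and 2 adjusted over the list alone, 11 and 6 with the clone block; camera adjusted p = 0.0238, and adjusted p = 0.377 with an estimated correlation). Zim1 went from 4.83 to 1.11 RPKM, Osbpl5 rose from 64.5 to 105 RPKM and the maternally expressed H19 fell. After deletion of Ctcf and Wapl 5 fell and 4 rose (7 and 4 adjusted over the list alone). Phlda2, a brake on placental growth, rose from 0.171 to 8.46 RPKM, and the paternally expressed Sgce and Peg3 fell from 32.5 to 5.38 and from 44.1 to 8.11 RPKM. The list passed camera (adjusted p = 0.0162), but not with the clone block (adjusted p = 0.0686), after median-of-ratios rescaling (adjusted p = 0.0569) or with an estimated correlation (adjusted p = 0.381). After Ctcf deletion Sgce and Peg3 were the 2 members that fell. Allele-specific expression was not measured.

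The ribosomal RNA precursor Rn45s took 3339 TPM of the untreated GRO-seq column of Ctcf and Wapl floxed cells, 492 after Adeno-Cre, 306 in DRB and 543 after its removal, against 16097 in the wild-type column. The wild-type table also lists RPKM values, which equalled the mean of the 4 untreated wild-type and Cre-ER RNA-seq libraries within 1 percent for 20282 of 20282 genes.

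A hypothesis written before its result was seen was that loss of CTCF or cohesin changes neighbouring genes together or apart, as loss of a boundary might. Positions came from the GRCm38.p6 reference, in which 12594 of the 12604 tested genes were found. After 522 pairs with a shared family name, and pairs of overlapping genes, were left out, 10942 neighbouring pairs remained. Called genes were placed at random 1000 times, matched on expression. After Ctcf deletion 109 pairs were both called, against a mean of 64.6 and a central range of 50 to 79. The excess lay in pairs of the same direction (77 against 35.4, 25 to 47), while pairs of opposite direction numbered 32 against 29.2 (20 to 39). In the libraries labelled Smc3-deleted 289 pairs were called against 247.2 (220 to 274), where pairs of opposite direction exceeded their range (137 against 115.6, 96 to 134) and those of the same direction did not (152 against 131.7, 110 to 152). Adeno-Cre in wild-type cells gave 12 against 11.3 (5 to 18), where few genes were called. These counts are in line with a shared change of neighbours after loss of Ctcf, but neighbours can share a regulator without a boundary, and boundaries were not measured here. Wapl deletion gave 4 pairs against 6.4, and deletion of Ctcf and Wapl gave 293 against 275.9 (247 to 306), with 187 of the same direction against 152.8 (130 to 176).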
